A study of Danio rerio with 4 samples.

How the data were processed

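Total RNA from whole zebrafish embryos was made into stranded libraries with a low-input total RNA kit from 10 ng of RNA and sequenced as single-end reads of 75 bases, per the labels. The deposited table gives a score per gene and library, and its values are read here as gene read counts that the authors divided by a size factor per library and rounded, from the pattern of the values alone. Single whole numbers are skipped at regular steps in both Cre-injected columns and overfilled at regular steps in both uninjected ones. Fitting these steps gave estimated size factors of 1.02, 1.03 for the uninjected and 0.983, 0.985 for the Cre-injected libraries, and so estimates of 9.28 M, 9.74 M, 8.78 M and 9.71 M assigned reads. The submitters' processing notes name FastQC 0.11.8, Trimmomatic 0.36, STAR 2.6.0c, featureCounts 1.6.0, DESeq2 1.14.1 and the builds danRer11 and GRCz11, without roles, and the table carries Ensembl identifiers and positions. The strand setting is not given in the sources used here. Each of the 20390 listed genes reaches 5 in at least 1 library.

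The columns carry the sample titles, which gave the groups. Nothing in the labels says that replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical. Replicates differed beyond counting noise, with a chi-square per gene of 7.68 between the uninjected and 17 between the Cre-injected libraries. These are means over genes in which the most abundant, such as mitochondrial ribosomal RNA, weigh most, so they do not describe a typical gene. Across genes, Pearson's r of log2 values was 0.98 and 0.976 within groups and 0.947 to 0.952 between them, where genes are not independent replicates. Mitochondrial ribosomal RNA took 12.3% and 16.4% of the uninjected and 12% and 16.1% of the Cre-injected totals.

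The planned count model was replaced by the fallback fixed with it, because the values are normalised: limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend and robust shrinkage, for genes of at least 10 in at least 2 libraries. A fold change on this scale understates the change of low genes. Benjamini-Hochberg adjusted p under 0.05 was the threshold. On simulated data for this comparison with 16754 genes, 61 of 100 genes changed 2-fold and 89 of 100 changed 4-fold were recovered, and 8 of 16136 unchanged genes were called. Further genes were given smaller shifts. The simulated libraries were independent, and genes of like level shared the same spread, so these rates may be better than those in the real data. The 19 gene lists were fixed before the data were examined, as were the test and the rule for named genes. The rule takes npas4l and hsp70l, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 2 CPM, a symbol that is not a clone name and groups that do not overlap, and in each list up to 4 members with the smallest p. Other list members, and mab21l1, were named after their values were seen. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, on the same log2 values, adjusted over the 19 lists. No list passed camera with an estimated correlation. This version rests on the few residual degrees of freedom of 4 libraries, so it has little power here. For the interferon list the estimate was -0.08, under the preset, yet the unadjusted camera p rose from 0.00115 to 0.075. A call lost this way thus need not be due to correlation between genes. Fry p-values are for a shift in 1 direction unless called mixed. The results of 1 list and its members are not reported here.

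Members were matched by symbol, then by alias, then by Ensembl identifier through a table of gene names. The transgene's gene npas4l and the list member ets1 stand under clone names and were found by identifier. Counting intervals treat the values as counts, since the estimated size factors lie within 2.75% of 1, and cover counting error only. Alternatives were other scalings, filters, thresholds and pseudocounts, shrinkage without the robust option, a replicate block and leaving out each library, and values in brackets after genes in sentences on a left-out library are log2 fold changes of that fit. Figures were drawn with matplotlib 3.10.9.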

Results

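RNA was sequenced from whole zebrafish embryos that carry a transgene in which the heat-inducible hsp70l promoter is kept from driving npas4l and a linked mCherry reporter by a stop cassette between loxP sites. Npas4l is a bHLH-PAS transcription factor needed to form endothelial and blood cells, and Cre is a recombinase that removes sequence between loxP sites. All embryos were raised at 28 °C, heat-shocked at 37 °C for 1 h and collected at the 6-somite stage. There were 2 libraries from embryos injected with Cre and 2 from uninjected embryos of the same line. The values summed to 9093935 and 9479827 in the uninjected libraries and to 8933474 and 9861419 in the Cre-injected ones, over 20390 genes. The design addresses which transcripts change when the npas4l transgene can be switched on in the whole embryo. It holds no injected embryos without the transgene, so effects of the injection, Cre and npas4l cannot be told apart in any difference below. The labels do not say whether the groups share parents or a clutch. A difference between clutches or in exact stage therefore cannot be told apart from them either.

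Transcript levels of npas4l itself were higher in both Cre-injected libraries. The gene (listed under the clone name CABZ01080135.1; chromosome 13, 52006253 to 52017013, GRCz11) stood at 370 and 279 normalised reads in the uninjected libraries and at 710 and 808 in the Cre-injected ones, a log2 fold change 1.23 ± 0.16 (SE), adjusted p = 0.00051 by limma. Reads of the endogenous gene and of the transgene's coding sequence are not separated in these values. Across the embryo, 1064 genes were higher and 1037 lower in Cre-injected embryos out of 16754 tested, and 323 and 450 of them differed by at least 1 on the log2 scale. A fit that leaves 1 library in a group takes its spread from the other group alone. Calls lost or gained in such fits, here and below, thus also reflect which pair of libraries sets the spread. The counts above rest on 2 libraries per group. Without uninjected replicate 1 or 2 they were 279 and 218, or 228 and 210, and without Cre-injected replicate 1 or 2 they were 2064 and 1871, or 1519 and 1738.

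The largest rises chosen by the fixed rule included genes that were nearly silent in uninjected embryos. The endoderm transcription factor gene sox32 had values of 3 and 0 without and 16 and 93 with Cre, a ratio of 36.3 (95% exact counting interval 12.1 to 179). For nkpd1 and pnp4a the ratios were 55 (95% exact counting interval 14.9 to 459.8) and 48.5 (95% exact counting interval 13.1 to 406). The monocarboxylate transporter gene slc16a9a, the cytochrome P450 gene cyp4v7 and the EGF-family ligand gene hbegfa rose by log2 fold changes of 3.30 ± 0.48, 3.24 ± 0.79 and 3.11 ± 0.65 (SE). The galectin gene lgals9l1 went from 23 ± 1.41 to 229 ± 93.3 (SD, n = 2; adjusted p = 4.86e-05). The sodium-calcium exchanger gene slc8a2b (2.54) and the multimerin gene mmrn2b (adjusted p = 0.00067) completed the rises together with the chaperone gene hsp70.1 (3.03). Among the falls, the apolipoprotein gene apoa4a (chromosome 19, 10845953 to 10850834) dropped from 219 ± 60.8 to 5 ± 2.83 (SD, n = 2; log2 fold change -5.25 ± 0.40 (SE), adjusted p = 1.94e-05), and its neighbour apoea fell as well (-3.41). The neurobeachin gene nbeab (chromosome 15, 32895659 to 33325046) went from 549.5 ± 81.3 to 24.5 ± 4.95 (SD, n = 2; log2 fold change -4.44 ± 0.22 (SE), adjusted p = 6.18e-07), and mab21l1, which lies inside it on the other strand, was lower too (-2.55). Genes for plasma and complement proteins, namely vtna (-3.48), c4 (-3.31) and cfd (-3.05), fell too, as did gc2 (-3.44), tnni1b, sptb and hbae3. Of the 80 genes named under the rule that passed the test, 25 passed it whichever library was left out, among them npas4l, nkpd1, slc16a9a, lgals9l1, slc8a2b, apoa4a, nbeab, apoea, cfd, hbae3, sox7, etv2, hbbe3, cdh17, tnnc2, myl10, apoa2, rbp4, hsp70.3, isg15, irf1b. Left out, uninjected replicate 1 took away the calls of cyp4v7 (1.74), hsp70.1 (2.74), mab21l1 (-2.50), gc2 (-2.96), c4 (-3.27), tnni1b (-3.16), sptb (-3.25). Left out, uninjected replicate 2 took away the calls of sox32 (3.32), mab21l1 (-2.60), vtna (-3.34), gc2 (-3.91), c4 (-3.36), tnni1b (-3.36), sptb (-3.16). Left out, Cre-injected replicate 1 took away the calls of mmrn2b (2.61). Left out, Cre-injected replicate 2 took away the calls of sox32 (3.09), pnp4a (3.58), hbegfa (2.16), mmrn2b (2.40), hsp70.1 (1.88). Among the other calls, fold changes moved by over 1.5 times for sox32 (log2 5.32 without uninjected replicate 1 and 5.55 without Cre-injected replicate 1), nkpd1 (log2 4.18 without uninjected replicate 1 and 5.77 without uninjected replicate 2), cyp4v7 (log2 4.74 without uninjected replicate 2), pnp4a (log2 5.23 without Cre-injected replicate 1), hbegfa (log2 4.07 without Cre-injected replicate 1), hsp70.1 (log2 4.18 without Cre-injected replicate 1), gc2 (log2 -2.64 without Cre-injected replicate 1 and -4.23 without Cre-injected replicate 2), cfd (log2 -3.66 without Cre-injected replicate 1 and -2.44 without Cre-injected replicate 2), sptb (log2 -2.34 without Cre-injected replicate 1 and -4.07 without Cre-injected replicate 2), hbae3 (log2 -3.83 without Cre-injected replicate 1 and -2.24 without Cre-injected replicate 2).

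Of the regulator genes that start blood and vessel development, 3 rose. They were sox7, from 104 ± 19.1 to 306 ± 95.5 (SD, n = 2; log2 fold change 1.53 ± 0.23 (SE), adjusted p = 0.00135), the ETS factor gene etv2, from 190 ± 65.1 to 453 ± 52.3 (log2 fold change 1.29 ± 0.21 (SE), adjusted p = 0.00238), and lmo2, from 190.5 ± 40.3 to 368 ± 38.9 (log2 fold change 0.96 ± 0.18 (SE), adjusted p = 0.00498). The Src-family kinase gene yrk (-0.94) and ets1 (-1.45) fell. For tal1 the values were 266 ± 4.24 and 369.5 ± 38.9 (adjusted p = 0.0603), and for fli1a 186 ± 19.1 and 162 ± 14.1 (adjusted p = 0.518). In all, 17 members of the haemato-endothelial list were tested, with 4 higher and 4 lower when adjusted over the list alone. The list has a median of -0.02 and a mean of 0.11. Camera gave adjusted p = 0.747 (up), and adjusted p = 0.766 with an estimated correlation (fry adjusted p = 0.154, up). Fry's mixed version, which counts changes both ways, gave adjusted p = 0.0391. Leaving out uninjected replicate 1 gave higher and lower counts of 2 and 0 (haemato-endothelial). Leaving out uninjected replicate 2 gave higher and lower counts of 3 and 0 (haemato-endothelial). Leaving out Cre-injected replicate 1 gave higher and lower counts of 4 and 4 (haemato-endothelial). Leaving out Cre-injected replicate 2 gave higher and lower counts of 3 and 3 (haemato-endothelial). The camera direction changed for the haemato-endothelial list without Cre-injected replicate 1 (adjusted p = 0.847). Calls lost without uninjected replicate 1 were those of lmo2 (0.74), yrk (-0.88), ets1 (-1.55). Calls lost without uninjected replicate 2 were those of yrk (-0.99), ets1 (-1.34). Calls gained without Cre-injected replicate 1 were those of tal1 (0.58). Fold changes of other calls moved by over 1.5 times for ets1 (log2 -0.86 without Cre-injected replicate 2). Under other settings calls ended for ets1 (adjusted p = 0.0503 with non-robust shrinkage).

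**Figure D1:**
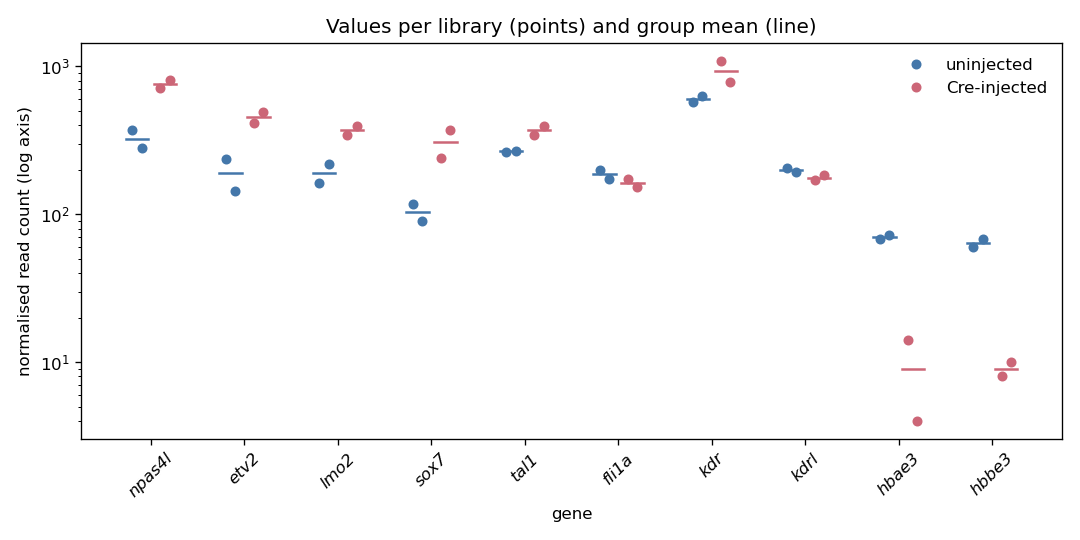
Normalised read count (log axis) of 10 genes in each library, with uninjected libraries in blue and Cre-injected ones in red, points for libraries and lines for group means. Both Cre-injected values of npas4l (710 and 808) lie above both uninjected ones, and those of hbae3 (14 and 4) lie below.

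Few genes on the list of differentiated endothelial markers passed the test. Among 35 tested markers, the VEGF receptor gene kdr, also a member of the VEGF and apelin list, rose, from 602 ± 43.1 to 934 ± 214 (SD, n = 2; log2 fold change 0.62 ± 0.15 (SE), adjusted p = 0.0225). The mannose receptor gene mrc1a fell (-3.67), on few reads: 11 and 26 in uninjected and 1 and 0 in Cre-injected libraries. The values of kdrl, another VEGF receptor gene, were 199.5 ± 7.78 and 176 ± 10.6 (adjusted p = 0.532), and those of cdh5, which encodes VE-cadherin, 131 ± 18.4 and 88 ± 25.5 (adjusted p = 0.134). This list had 1 higher and 1 lower when adjusted over the list alone, and camera gave adjusted p = 0.0556 (down), and adjusted p = 0.474 with an estimated correlation (fry adjusted p = 0.145, down). Over the scalings tried 1 to 2 of its members were lower. Of the embryonic red-cell genes, 5 of 21 fell, 1 rose and 15 passed in neither direction. The globin genes hbae3 and hbbe3 went from 70 ± 2.83 to 9 ± 7.07 and from 64 ± 5.66 to 9 ± 1.41 (SD, n = 2), with log2 fold changes of -3.03 ± 0.50 and -2.70 ± 0.38 (SE). Also lower were the spectrin gene sptb, the haem synthesis gene cpox (-0.66) and the transferrin receptor gene tfr1a (-1.12), while the carbonic anhydrase gene cahz rose (0.59). With 1 higher and 6 lower when adjusted over the list alone, camera gave adjusted p = 0.0441 (down), and adjusted p = 0.474 with an estimated correlation (fry adjusted p = 0.0821, down). Only 6 members of the myeloid and definitive blood list were tested. Of these lcp1, for the actin-bundling L-plastin, rose (1.08), and the transcription factor genes myb (-0.87), spi1b (-1.58) and runx1 (-1.52) fell. For this list camera gave adjusted p = 0.639 (down), and adjusted p = 0.708 with an estimated correlation (fry adjusted p = 0.154, down), with 2 higher and 3 lower when adjusted over the list alone. When uninjected replicate 1 was left out, the higher and lower counts were 0 and 0 (endothelial), 0 and 2 (erythroid), 1 and 1 (myeloid). When uninjected replicate 2 was left out, the higher and lower counts were 0 and 0 (endothelial), 0 and 2 (erythroid), 0 and 0 (myeloid). When Cre-injected replicate 1 was left out, the higher and lower counts were 1 and 6 (endothelial), 2 and 5 (erythroid), 2 and 3 (myeloid). When Cre-injected replicate 2 was left out, the higher and lower counts were 1 and 3 (endothelial), 1 and 7 (erythroid), 1 and 2 (myeloid). The camera call was lost for the erythroid list without uninjected replicate 1 (adjusted p = 0.065), the erythroid list without uninjected replicate 2 (adjusted p = 0.0595) and the erythroid list without Cre-injected replicate 1 (adjusted p = 0.186). A camera call was gained for the endothelial list without uninjected replicate 2 (adjusted p = 0.035) and the endothelial list without Cre-injected replicate 1 (adjusted p = 0.0344). Once uninjected replicate 1 was dropped, the test was no longer passed by kdr (0.54), mrc1a (-4.25), sptb (-3.25), cpox (-0.55), tfr1a (a fold of 0.499 against 0.462 with all libraries), cahz (0.65), myb (-0.86), runx1 (-1.54). Once uninjected replicate 2 was dropped, the test was no longer passed by kdr (0.69), mrc1a (-3.08), sptb (-3.16), cpox (-0.76), tfr1a (-1.23), cahz (0.53), lcp1 (0.84), myb (-0.87), spi1b (-1.10), runx1 (-1.50). Once Cre-injected replicate 2 was dropped, the test was no longer passed by runx1 (-1.06). Once Cre-injected replicate 2 was dropped, the test was newly passed by cdh5 (-0.89). Moves of over 1.5 times in fold change, with the call kept, were those of hbae3 (log2 -3.83 without Cre-injected replicate 1 and -2.24 without Cre-injected replicate 2), sptb (log2 -2.34 without Cre-injected replicate 1 and -4.07 without Cre-injected replicate 2). Calls that ended under other settings were those of runx1 (adjusted p = 0.0631 with non-robust shrinkage, adjusted p = 0.0502 with upper-quartile scaling).

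Single genes of the other mesoderm lists rose or fell. Heart genes counted 4 lower and 1 higher of 17: the troponin gene tnni1b fell from 42 ± 4.24 to 3.5 ± 0.707 (SD, n = 2; log2 fold change -3.26 ± 0.51 (SE), adjusted p = 0.00178), tbx5a (-2.22) and mef2cb (-0.62) fell, and gata4 rose (0.60). For the heart list camera gave adjusted p = 0.27 (down), and adjusted p = 0.708 with an estimated correlation (fry adjusted p = 0.149, down), with 1 higher and 5 lower when adjusted over the list alone. In the kidney primordium list, lhx1a (1.06), pax8 (0.85) and hnf1bb (0.59) rose and the cadherin gene cdh17 fell (-1.19), of 16 tested. Its median was 0.03, and ranged from -0.01 to 0.03 over the scalings tried, its mean was -0.07, and camera gave adjusted p = 0.907 (up), and adjusted p = 0.92 with an estimated correlation (fry adjusted p = 0.909, down), with 3 higher and 3 lower when adjusted over the list alone. In the paraxial mesoderm and muscle list, the troponin gene tnnc2 (log2 fold change -1.47 ± 0.18 (SE), adjusted p = 0.000436), the myosin light chain gene myl10 (-1.09) and the actin genes acta1a (-0.70) and acta1b (-0.80) fell, while the myosin genes smyhc1 and mylpfa had log2 fold changes of 0.01 and -0.19 (adjusted p = 0.985 and 0.836). The presomitic mesoderm gene msgn1 (0.48), the fibronectin gene fn1b (0.42) and the myosin chaperone gene unc45b (0.53) rose. In total 7 of 25 paraxial mesoderm and muscle genes fell and 3 rose (1 to 3 higher over the scalings tried), with 3 higher and 10 lower when adjusted over the list alone, and camera gave adjusted p = 0.0431 (down), and adjusted p = 0.518 with an estimated correlation (fry adjusted p = 0.116, down). A single notochord gene of 12, emilin3a, rose (0.84); camera gave adjusted p = 0.116 (up), and adjusted p = 0.631 with an estimated correlation (fry adjusted p = 0.437, up), with 1 higher and 0 lower when adjusted over the list alone. With uninjected replicate 1 left out, higher and lower genes numbered 0 and 0 (heart), 1 and 1 (kidney primordium), 0 and 2 (muscle), 0 and 0 (notochord). With uninjected replicate 2 left out, higher and lower genes numbered 0 and 0 (heart), 0 and 1 (kidney primordium), 0 and 3 (muscle), 0 and 0 (notochord). With Cre-injected replicate 1 left out, higher and lower genes numbered 2 and 6 (heart), 4 and 4 (kidney primordium), 4 and 9 (muscle), 1 and 0 (notochord). With Cre-injected replicate 2 left out, higher and lower genes numbered 2 and 2 (heart), 3 and 1 (kidney primordium), 5 and 9 (muscle), 6 and 0 (notochord). The camera call was lost for the muscle list without uninjected replicate 1 (adjusted p = 0.0546), the muscle list without uninjected replicate 2 (adjusted p = 0.0595) and the muscle list without Cre-injected replicate 2 (adjusted p = 0.323). A camera call was gained for the notochord list without Cre-injected replicate 2 (adjusted p = 0.00412). The camera direction changed for the kidney primordium list without uninjected replicate 2 (adjusted p = 0.932) and the kidney primordium list without Cre-injected replicate 1 (adjusted p = 0.942). Left out, uninjected replicate 1 took away the calls of tnni1b (-3.16), tbx5a (-2.17), mef2cb (-0.55), gata4 (0.74), pax8 (0.84), hnf1bb (0.71), acta1a (-0.60), acta1b (-0.76), msgn1 (0.43), fn1b (0.44), unc45b (0.54), emilin3a (0.78). Left out, uninjected replicate 2 took away the calls of tnni1b (-3.36), tbx5a (-2.27), mef2cb (-0.68), gata4 (0.46), lhx1a (0.92), pax8 (0.86), hnf1bb (0.48), acta1b (-0.84), msgn1 (0.53), fn1b (0.40), unc45b (0.52), emilin3a (0.90). Left out, Cre-injected replicate 2 took away the calls of mef2cb (-0.51). Left out, Cre-injected replicate 2 added calls of smyhc1 (0.30). Other settings ended the calls of mef2cb (adjusted p = 0.0566 with scaling by library size, adjusted p = 0.0552 with non-robust shrinkage), msgn1 (adjusted p = 0.0551 with scaling by library size), fn1b (adjusted p = 0.0874 with scaling by library size, adjusted p = 0.0732 with non-robust shrinkage, adjusted p = 0.0737 with equal totals without mitochondrial and structural RNA genes), emilin3a (adjusted p = 0.0642 with no filter).

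In the ectodermal lists, more genes fell than rose, and most passed the test in neither direction. In the neural list 6 of 29 genes fell and none rose, among them the eye and forebrain gene pax6a, from 686 ± 16.3 to 412 ± 20.5 (SD, n = 2; log2 fold change -0.74 ± 0.13 (SE), adjusted p = 0.00331), zic1 (-0.60), the proneural gene neurog1 (-0.81) and sox19a (-0.41). There were 0 higher and 13 lower when adjusted over the list alone, and camera gave adjusted p = 0.000187 (down), and adjusted p = 0.474 with an estimated correlation (fry adjusted p = 0.116, down). Neural crest genes included 3 that fell, tfap2a (-0.46), sox10 (-0.50) and snai1b (-0.42), and 1 that rose, prdm1a (0.47), of 15. For them camera gave adjusted p = 0.0556 (down), and adjusted p = 0.474 with an estimated correlation (fry adjusted p = 0.00667, down), with 1 higher and 4 lower when adjusted over the list alone. Under the scalings tried, 1 to 3 crest genes were lower and 0 to 1 higher. Of 21 epidermal and hatching gland genes, 9 fell and 1 rose. The keratin gene krt4 went from 102654 ± 2162 to 62157 ± 5904 (log2 fold change -0.73 ± 0.12 (SE), adjusted p = 0.00204), with cyt1l (-0.76), krt92 (-0.68) and the epidermal regulator tp63 (-0.68) also lower and evpla, for envoplakin, higher (0.50). This list gave 2 higher and 12 lower when adjusted over the list alone, and camera gave adjusted p = 0.00236 (down), and adjusted p = 0.518 with an estimated correlation (fry adjusted p = 0.154, down). Endoderm genes sox32 and hnf4a (0.99) rose of 11, while sox17 had values of 8.5 ± 0.707 and 22.5 ± 7.78 (adjusted p = 0.125). Here camera gave adjusted p = 0.0459 (up), and adjusted p = 0.474 with an estimated correlation (fry adjusted p = 0.0821, up), with 2 higher and 0 lower when adjusted over the list alone. Yolk layer genes fell in 5 of 13 cases, among them apoa2, from 4340.5 ± 480.1 to 1441 ± 140.0 (log2 fold change -1.59 ± 0.12 (SE), adjusted p = 1.94e-05), the retinol carrier gene rbp4 (-2.82) and the fatty-acid carrier gene fabp1b.1 (-0.66). With 1 higher and 5 lower when adjusted over the list alone, camera gave adjusted p = 0.00681 (down), and adjusted p = 0.474 with an estimated correlation (fry adjusted p = 0.0118, down). Leaving out uninjected replicate 1 gave higher and lower counts of 0 and 0 (neural), 0 and 0 (crest), 2 and 0 (endoderm), 0 and 1 (epidermal), 0 and 2 (yolk layer). Leaving out uninjected replicate 2 gave higher and lower counts of 0 and 1 (neural), 0 and 0 (crest), 0 and 0 (endoderm), 0 and 0 (epidermal), 0 and 2 (yolk layer). Leaving out Cre-injected replicate 1 gave higher and lower counts of 0 and 12 (neural), 2 and 5 (crest), 3 and 2 (endoderm), 3 and 11 (epidermal), 2 and 4 (yolk layer). Leaving out Cre-injected replicate 2 gave higher and lower counts of 0 and 7 (neural), 1 and 5 (crest), 1 and 0 (endoderm), 1 and 12 (epidermal), 1 and 7 (yolk layer). The camera call was lost for the endoderm list without uninjected replicate 2 (adjusted p = 0.103), the endoderm list without Cre-injected replicate 1 (adjusted p = 0.129) and the yolk layer list without Cre-injected replicate 1 (adjusted p = 0.0702). A camera call was gained for the crest list without Cre-injected replicate 2 (adjusted p = 0.0406). Calls lost without uninjected replicate 1 were those of pax6a (-0.76), zic1 (-0.67), neurog1 (-0.61), sox19a (-0.40), tfap2a (-0.49), sox10 (-0.54), snai1b (-0.36), prdm1a (0.59), krt4 (-0.71), cyt1l (-0.77), krt92 (-0.63), tp63 (-0.75), evpla (0.52), fabp1b.1 (-0.77). Calls lost without uninjected replicate 2 were those of pax6a (-0.71), zic1 (-0.54), sox19a (-0.43), tfap2a (-0.43), sox10 (-0.45), snai1b (-0.48), prdm1a (0.35), krt4 (-0.75), cyt1l (-0.74), krt92 (-0.73), tp63 (-0.61), evpla (0.49), sox32 (3.32), hnf4a (0.72), fabp1b.1 (-0.56). Calls lost without Cre-injected replicate 2 were those of sox32 (3.09), hnf4a (0.56). Fold changes of other calls moved by over 1.5 times for sox32 (log2 5.32 without uninjected replicate 1 and 5.55 without Cre-injected replicate 1). Under other settings calls ended for sox10 (adjusted p = 0.057 with scaling by library size), snai1b (adjusted p = 0.0565 with scaling by library size, adjusted p = 0.0662 with non-robust shrinkage, adjusted p = 0.0506 with a replicate block), prdm1a (adjusted p = 0.0544 with scaling by library size), hnf4a (adjusted p = 0.0631 with non-robust shrinkage, adjusted p = 0.0505 with a replicate block), fabp1b.1 (adjusted p = 0.0526 with non-robust shrinkage).

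**Figure D2:**
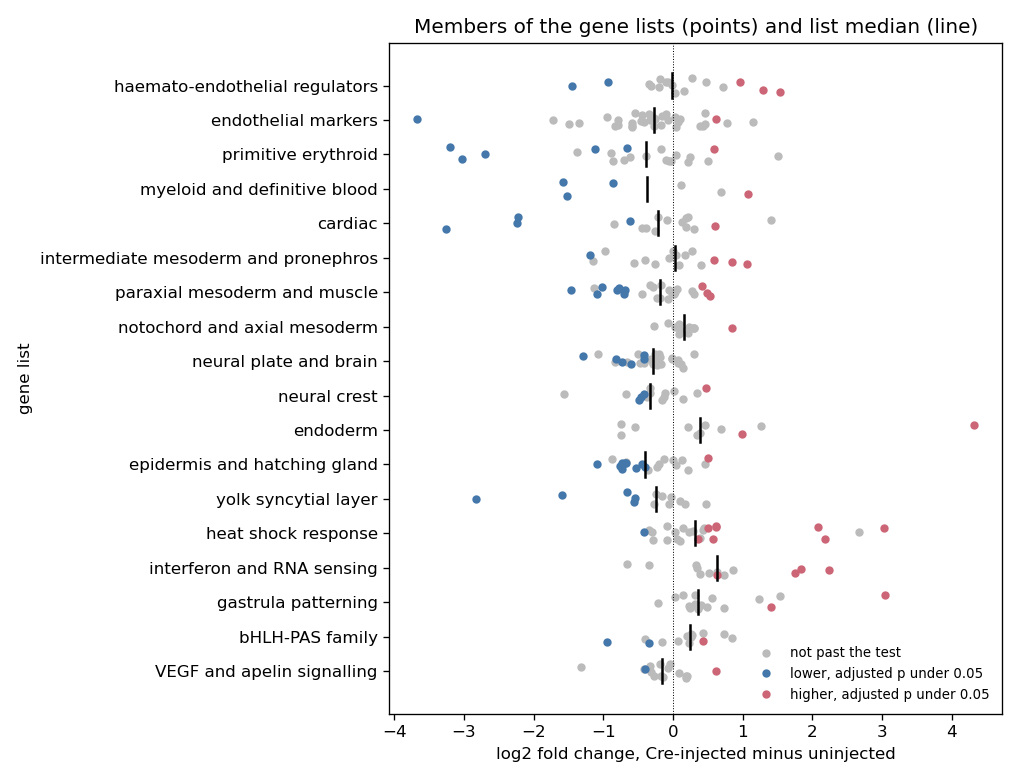
Log2 fold change, Cre-injected minus uninjected, of each tested member of 18 gene lists, coloured by its call at adjusted p under 0.05, with black lines at list medians. The epidermal list has the lowest median (-0.41).

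Chaperone and interferon-response genes rose in part. Heat-shock genes counted 8 higher and 1 lower of 24, with 9 higher and 2 lower when adjusted over the list alone, and camera gave adjusted p = 0.00376 (up), and adjusted p = 0.552 with an estimated correlation (fry adjusted p = 0.228, up). The chaperone gene hsp70l had 33 and 26 reads in uninjected libraries and 66 and 280 in Cre-injected ones (log2 fold change 2.18 ± 0.58 (SE), adjusted p = 0.0494). Its near-identical relatives hsp70.1 and hsp70.3 (2.08) may share reads with it, so their separate values are uncertain. Also higher were hsp90aa1.1 (0.62) and serpinh1b (0.57), a collagen chaperone gene. Under the scalings tried 6 to 8 members were higher and 1 to 2 lower. Interferon-response genes isg15 (log2 fold change 2.25 ± 0.25 (SE), adjusted p = 0.000202), irf1b (1.75), stat1a (0.63) and ifit8 (1.83) rose of 13. For this list camera gave adjusted p = 0.00376 (up), and adjusted p = 0.474 with an estimated correlation (fry adjusted p = 0.0367, up), with 4 higher and 0 lower when adjusted over the list alone. When uninjected replicate 1 was left out, the higher and lower counts were 1 and 0 (heat-shock), 3 and 0 (interferon). When uninjected replicate 2 was left out, the higher and lower counts were 2 and 0 (heat-shock), 2 and 0 (interferon). When Cre-injected replicate 1 was left out, the higher and lower counts were 14 and 2 (heat-shock), 3 and 0 (interferon). When Cre-injected replicate 2 was left out, the higher and lower counts were 6 and 3 (heat-shock), 3 and 0 (interferon). The camera call was lost for the heat-shock list without uninjected replicate 2 (adjusted p = 0.115), the heat-shock list without Cre-injected replicate 2 (adjusted p = 0.0516) and the interferon list without Cre-injected replicate 1 (adjusted p = 0.0572). Once uninjected replicate 1 was dropped, the test was no longer passed by hsp70l (2.35), hsp70.1 (2.74), hsp90aa1.1 (0.63), serpinh1b (0.66), stat1a (0.53). Once uninjected replicate 2 was dropped, the test was no longer passed by hsp70l (2.01), hsp90aa1.1 (0.61), serpinh1b (0.48), stat1a (0.72), ifit8 (1.28). Once Cre-injected replicate 1 was dropped, the test was no longer passed by ifit8 (1.81). Once Cre-injected replicate 2 was dropped, the test was no longer passed by hsp70.1 (1.88), ifit8 (1.86). Moves of over 1.5 times in fold change, with the call kept, were those of hsp70l (log2 3.21 without Cre-injected replicate 1 and a fold of 2.21 without Cre-injected replicate 2, against 4.53 with all libraries), hsp70.1 (log2 4.18 without Cre-injected replicate 1). Calls that ended under other settings were those of hsp70l (adjusted p = 0.135 with no filter, adjusted p = 0.0699 with pseudocount 5), ifit8 (adjusted p = 0.0525 with non-robust shrinkage).

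Few early patterning and signalling genes passed the test singly. The gastrula list as a whole lay higher, with a median log2 fold change of 0.35. It passed camera only at the preset correlation, but no list passed at an estimated one, where power is low. A difference in exact stage between the groups could also shift this list and the tissue lists above, and was not tested. In the gastrula list ved (1.40), a ventral homeobox gene, and ndr2 (3.04), a Nodal ligand gene with values of 0, 4, 13 and 23, rose of 17, while gsc had 7.5 ± 2.12 and 23.5 ± 4.95 (SD, n = 2; adjusted p = 0.0718). Over the scalings tried 1 to 3 members were higher. There were 4 higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 0.00112 (up), and adjusted p = 0.474 with an estimated correlation (fry adjusted p = 0.121, up). Relatives of npas4l in the bHLH-PAS family included hif1ab, a hypoxia factor gene that rose (0.43), and arntl1b (-0.95) and hif1al (-0.35), which fell, of 14. For the family camera gave adjusted p = 0.287 (up), and adjusted p = 0.518 with an estimated correlation (fry adjusted p = 0.121, up), with 1 higher and 2 lower when adjusted over the list alone. Among 16 VEGF and apelin signalling genes, kdr rose and the PDGF receptor gene pdgfra fell (-0.40), with 1 higher and 1 lower when adjusted over the list alone, and camera gave adjusted p = 0.375 (down), and adjusted p = 0.708 with an estimated correlation (fry adjusted p = 0.422, down). The scalings tried gave 1 to 2 lower genes in the bHLH-PAS family and 0 to 1 in the VEGF and apelin list. With uninjected replicate 1 left out, higher and lower genes numbered 1 and 0 (gastrula), 0 and 0 (bHLH-PAS), 0 and 0 (VEGF and apelin). With uninjected replicate 2 left out, higher and lower genes numbered 1 and 0 (gastrula), 0 and 0 (bHLH-PAS), 0 and 0 (VEGF and apelin). With Cre-injected replicate 1 left out, higher and lower genes numbered 7 and 0 (gastrula), 2 and 3 (bHLH-PAS), 2 and 2 (VEGF and apelin). With Cre-injected replicate 2 left out, higher and lower genes numbered 1 and 0 (gastrula), 3 and 2 (bHLH-PAS), 2 and 1 (VEGF and apelin). Left out, uninjected replicate 1 took away the calls of ndr2 (1.87), hif1ab (0.41), arntl1b (-1.04), hif1al (-0.40), kdr (0.54), pdgfra (-0.38). Left out, uninjected replicate 2 took away the calls of ved (1.07), hif1ab (0.45), arntl1b (-0.85), hif1al (-0.31), kdr (0.69), pdgfra (-0.43). Left out, Cre-injected replicate 2 took away the calls of ndr2 (2.65). Among the other calls, fold changes moved by over 1.5 times for ndr2 (log2 4.20 without uninjected replicate 2). Other settings ended the calls of ndr2 (adjusted p = 0.0601 with pseudocount 0.5, adjusted p = 0.0616 with non-robust shrinkage, adjusted p = 0.0511 with equal totals without mitochondrial and structural RNA genes), hif1al (adjusted p = 0.0623 with scaling by library size, adjusted p = 0.0521 with recomputed median of ratios, adjusted p = 0.0501 with pseudocount 0.5, adjusted p = 0.069 with non-robust shrinkage, adjusted p = 0.0511 with trimmed mean of M-values, adjusted p = 0.0668 with a replicate block), pdgfra (adjusted p = 0.087 with scaling by library size, adjusted p = 0.0506 with recomputed median of ratios, adjusted p = 0.065 with non-robust shrinkage, adjusted p = 0.0511 with trimmed mean of M-values, adjusted p = 0.0606 with upper-quartile scaling, adjusted p = 0.0546 with a replicate block).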

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

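The log2 fold change of npas4l stayed past the threshold in all alternatives run, from 1.03 to 1.44, and no named gene's called direction turned in any of them. At adjusted p under 0.01 there were 412 genes higher and 449 lower, by the construction of that threshold. Leaving out 1 library at a time gave 228 to 2064 genes higher and 210 to 1871 lower. The low ends came without an uninjected library and the high ends without Cre-injected replicate 1, and the lone library left in a group is then assumed to vary like the other group. Of the 2101 changed genes, those still called in each of the 4 fits that left out 1 library kept their direction. Far fewer were still called without an uninjected library than without a Cre-injected one. Rising members of the haemato-endothelial list numbered 2 to 4 over the 4 fits. Other scalings gave 863 to 1090 genes higher and 968 to 1075 lower. The pseudocounts 0.5 and 5 and the trimmed mean of M-values were chosen after seeing the data. Shrinkage without the robust option gave 825 genes higher and 836 lower, and 9 named genes lost their call, against at most 5 under a scaling and 28 at adjusted p under 0.01. With the replicate number as a block, 4 named genes lost their call and 1132 genes were higher and 1121 lower. The deviations of same-numbered libraries correlated at -0.03 over genes, and the numbers are not known to pair the samples. Camera calls of 10 lists were lost with an estimated correlation, a version with little power here. Fry called 4 lists in 1 direction. Its mixed version, which counts changes both ways, gave adjusted p = 0.0391 for the haemato-endothelial and 0.00732 for the kidney primordium list. It gave 0.0689, 0.456 and 0.254 for the endoderm, notochord, and VEGF and apelin lists, the only lists over 0.05. The mixed version does not ask whether a list changed more than other genes. The planned count-model and voom fits were not run because they need raw counts. With 2 libraries per group, simulated changes of 2-fold were recovered in 61 of 100 genes.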

Other observations

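The gene groups and single genes of this paragraph were chosen after their values were seen. Core histone genes, known from their descriptions and symbols, were lower in 39 and higher in 2 of 79 tested cases, with a median log2 fold change of -0.61 and, under the scalings tried, 39 to 40 lower. Their copies are nearly identical, so single values are uncertain, and their summed value was 0.819 times that of uninjected embryos. Of 76 cytosolic ribosomal protein genes 28 were lower and 0 higher (median -0.31; 23 to 32 lower under the scalings tried). Next to each other on chromosome 2, the long noncoding RNA genes CU927934.1 and CU927934.3 went from 4 and 1 to 178 and 280, and from a listed 0 in both uninjected libraries to 69 and 109. BX511034.1 on chromosome 22 went the other way, from 49 and 48 to a listed 0 in both Cre-injected libraries. The galectin gene lgals9l3, neighbour of lgals9l1, rose by 1.74 ± 0.27 (SE, log2). Calls lost without uninjected replicate 1 were those of BX511034.1 (-5.61). Calls lost without uninjected replicate 2 were those of BX511034.1 (-5.64). Fold changes of other calls moved by over 1.5 times for CU927934.1 (log2 6.81 without uninjected replicate 1 and 5.49 without uninjected replicate 2). Without uninjected replicates 1 and 2 and Cre-injected replicates 1 and 2 in turn, 17, 19, 39 and 53 histone genes and 2, 3, 33 and 53 ribosomal protein genes were lower, and without Cre-injected replicate 1, 9 histone and 7 ribosomal protein genes were higher.

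All tests below were chosen after their results were seen. Chromosome 25 was picked because its median was the lowest of all nuclear chromosomes: over 278 protein-coding genes with assigned symbols, histones left out, the median was -0.16, against 0.00 to 0.09 on the other 24. The shift rests mostly on Cre-injected replicate 1 (-0.23, against -0.05 in replicate 2). The chromosome also differed between the uninjected libraries (median -0.05, replicate 2 minus 1). A share of 0.0014 of matched gene sets was as low, against 0.001 for Cre-injected replicate 2. A shift of the size in replicate 2 may thus arise without the injection, but 1 pair of libraries cannot show how often. A share of 0.0001 of 10000 gene sets matched on expression level, the smallest they can give, had a median as low. Gene sets of like level from the other chromosomes thus did not reach so low a median, within the limits given below. Whichever window of 4 Mb was left out, the median stayed at -0.13 to -0.18 with the same share, so no single window carries the shift. Because the chromosome was picked for its low median, and genes are treated as independent, this share does not measure chance. The windows of 4 Mb differed (permutation p = 0.0005, the smallest that 2000 permutations give, with 2 of the other 24 chromosomes under 0.05, and 0.0005 and 0.016 in Cre-injected replicates 1 and 2, 0.328 between the uninjected libraries). Medians below and from 24 Mb were -0.32 and -0.07 in replicate 1 and -0.08 and 0.10 in replicate 2. This does not decide on an equal loss of the whole chromosome in part of the cells, since regional differences in expression could also make windows differ. A first test of 24 to 32 Mb, a window picked from these values, gave a permutation p of 0.0016. All these permutation tests treat neighbouring genes as independent. An equal loss in part of the cells, a change of part of the chromosome in some cells and a difference in parental chromosomes may each apply. They stay open, as no DNA was measured.

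Copies of RF00017, the 7SL RNA of the signal recognition particle, summed to 142080 and 134548 in uninjected and 52101 and 69575 in Cre-injected libraries. Reads moving among the listed near-identical copies would leave the sum in place, but it differed by -1.20 on the log2 scale, more than the largest replicate difference of 0.42. Reads that moved to unlisted copies, or were dropped because they match several, would change the sum, so such shifts stay open. Of 5 other short RNA classes, 4 were lower in both Cre-injected libraries (snoRNA, scaRNA, ribozyme and mitochondrial tRNA genes), while miRNA genes summed to 95 and 123 against 92 and 97. A lower recovery of short structured RNAs in the libraries and a lower level in the embryos cannot be told apart from these values (4 of 5 classes).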
